A study of Homo sapiens with 10 samples.

How the data were processed

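Total RNA of 10 libraries was measured, from the pancreatic adenocarcinoma lines CFPAC-1 and PANC-1 after 24 h with imidazole ketone erastin (IKE) or 0.1% DMSO. Per the labels' protocols, RNA was extracted with Trizol, depleted of rRNA, reverse transcribed with random primers and made into libraries whose second strand was digested with uracil-N-glycosylase. These libraries keep the strand, but whether strand was used in counting is not given in the sources used here, so values of genes that overlap others are uncertain. Per the submitters' processing notes, the tools were fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.1.0, StringTie 1.3.4 and DESeq2 (no version), with the build GRCh38. The role of each tool, the annotation and any filter are not given in the sources used here. The deposited table holds FPKM values made by the authors, rounded to 2 decimals, for 20289 Ensembl genes in 10 sample columns. A further 9 columns are empty and were not used. Of the genes, 20257 have a symbol, 19783 are protein-coding in GENCODE 29, 388 have another type there, 118 are not in that release and 2627 are listed at 0 in all libraries. Counts are not in the table, so depth is unknown and counting error cannot be given. FPKM totals ran from 405937 to 472665 per library.

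Samples were grouped by line and treatment as the labels give them. The labels call the replicates bioreplicates and do not say whether they are separate cultures, so p-values measure only the spread between these samples, whether technical or biological. The planned test assumed counts, and since the table holds FPKM, the test planned for normalized values was used. Genes with at least 1 FPKM in at least 2 libraries were kept, 13077 in all, and values were log2-transformed after adding 1. limma 3.58.1 in R 4.3.3 was fitted to all 10 libraries with a mean per group and an intensity trend in the variance prior (6 residual and 5.1 prior degrees of freedom). Tests were two-sided, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. The contrasts were IKE against DMSO in each line, the difference of these between the lines, and PANC-1 against CFPAC-1 with DMSO. Genes changed in both lines were counted per direction and compared with independent lists by a one-sided Fisher's exact test. All p-values for single genes are from limma.

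The 33 gene lists covered the ATF4 amino acid response, aminoacyl tRNA synthetases, NRF2 targets, glutathione, ferroptosis suppressors and drivers, iron and haem, cholesterol, fatty acids, the unfolded protein response, p53 targets, apoptosis, G1/S, G2/M, replication-dependent histones, immediate early genes, NF-kB, interferon, heat shock, metallothioneins, hypoxia, glycolysis, nuclear and mitochondrially encoded respiratory chain genes, ribosomal proteins, ribosome biogenesis, autophagy and lysosome, ESCRT-III, YAP and TAZ targets, epithelial and mesenchymal genes, other cell types, and nuclear-retained RNAs. Each list was tested with camera of the same limma version, two-sided, at a preset correlation of 0.01, adjusted over the 33 lists within a comparison, and again with an estimated correlation and with fry. The count of called members is given over all genes tested and adjusted over the list alone. Some genes belong to several lists, so results of lists are not independent of each other.

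The named genes follow a rule. They are a panel of 21 genes of cystine uptake, the ATF4 response, iron and lipid peroxidation, the 8 called genes with the largest rise and the 8 with the largest fall in each comparison (mean of at least 1 on the log2 scale in that line, each treated library beyond each control library, no clone names), up to 4 called members with the smallest p for each described list, and the 6 genes with the smallest p per direction for the difference and for both lines. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

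The alternatives were quantile normalization, no low-value filter, at least 5 FPKM in 2 libraries, a pseudocount of 0.1, an absolute log2 fold change of at least 1, the replicate number as a block, a fit per line, PANC-1 IKE replicates 1 and 2 alone, and each library left out in turn. Median-ratio scaling of FPKM, PANC-1 IKE replicates 3 and 4 alone, and FPKM rescaled without RPS29 and PTPRD were added after the data were seen. Alternatives that need counts were not run. The fit was tested on simulated data with the DMSO means of each line and the spread of this table, 5 runs with 200 changed genes each in 13077. Changed genes were drawn from those with a mean above 1 on the log2 scale. The noise was independent between libraries, so genes with lower values and shared library effects were not covered. In CFPAC-1 it recovered 77.5% to 79.0% of genes changed 1.5-fold and 98.0% to 99.5% of those changed 2-fold, with 7.5% of calls false. In PANC-1 it recovered 88.0% to 91.0% and 99.0% to 100% of them, with 6.2% of calls false. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.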

Results

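RNA was sequenced from 2 human pancreatic ductal adenocarcinoma cell lines, CFPAC-1 and PANC-1, after 24 h with imidazole ketone erastin or with 0.1% DMSO, the solvent control. Imidazole ketone erastin (IKE) is a derivative of erastin that blocks system xc-, the exchanger that brings cystine into the cell in return for glutamate. Loss of cystine lowers glutathione and can lead to ferroptosis, an iron-dependent death by lipid peroxidation, and the series looks for its regulators in this cancer. CFPAC-1 received 10 µM IKE and PANC-1 received 1 µM. Dead cells and debris were removed, so that surviving cells were measured. A change with IKE can therefore lie within cells or in which cells survived, and these data cannot tell them apart. CFPAC-1 with DMSO, CFPAC-1 with IKE and PANC-1 with DMSO had 2 libraries each, and PANC-1 with IKE had 4. Expression is in FPKM, fragments scaled to transcript length and to the library's mapped total. Summed FPKM ran from 405937 to 472665 per library, and 11604 to 12248 genes reached 1 FPKM, while the read depth is unknown. Mitochondrially encoded mRNAs made up 2.65% to 5.27% of FPKM, with the highest share in PANC-1 IKE replicate 3. Changes are log2 fold changes of FPKM + 1 over 13077 tested genes, a scale that understates changes of genes with low values, and coordinates are for GRCh38 (GENCODE 29).

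The first comparison asked what changed in CFPAC-1 cells that survived 10 µM IKE, and genes of amino acid supply had the largest rises. ASNS, which makes asparagine (ENSG00000070669, chromosome 7, 97852118 to 97872542), went from 11.3 ± 0.247 to 68.4 ± 5.94 FPKM (mean ± SD, n = 2 in each group; log2 fold change 2.50, SE 0.11, adjusted p = 4.05e-07, limma). PSAT1 (log2 fold change 2.47, SE 0.11, adjusted p = 4.05e-07) and PHGDH (log2 fold change 2.24, SE 0.10, adjusted p = 4.05e-07), both of serine synthesis, also rose. The leucine carrier gene SLC7A5 rose by 1.98 on the log2 scale (adjusted p = 6.60e-07), and CBS, of the transsulfuration route to cysteine, by 1.89 on the log2 scale (adjusted p = 4.05e-07). ATF4, the transcription factor of the amino acid stress response (ENSG00000128272, chromosome 22, 39519695 to 39522685), rose from 92.7 ± 1.79 to 230.0 ± 3.17 FPKM (log2 fold change 1.3, SE 0.07, adjusted p = 2.98e-06). CHAC1, which degrades glutathione, rose from 0.745 ± 0.163 to 5.32 ± 0.177 FPKM (log2 fold change 1.86, adjusted p = 1.36e-04). The calcium-binding protein gene S100P (1.64, adjusted p = 0.00201) and the secreted glycoprotein gene STC2 (1.61, adjusted p = 2.98e-06) rose as well. WDR49 (-1.12, adjusted p = 8.75e-04), the collagen gene COL8A1 (-1.0, adjusted p = 3.48e-04), the potassium channel gene KCNJ15 (-0.93, adjusted p = 0.00128) and IRAG2 (-1.02, adjusted p = 0.00111) fell, from DMSO levels of 3.81, 2.29, 6.92 and 2.45 FPKM. In every gene named as risen or fallen with IKE, each IKE library lay beyond each DMSO library of its line. LGALS2 (-0.91, adjusted p = 0.0298), ABCB1 (-0.79, adjusted p = 0.0141), PLCXD2 (-0.78, adjusted p = 0.0449) and P2RX5-TAX1BP3 (-0.87, adjusted p = 0.0333) fell too. The last is a readthrough of neighbouring genes and so uncertain. Their calls, but not their signs, depended on which library was left out. Leaving out a CFPAC-1 library leaves 1 in its arm, which also lowers the power. LGALS2 lost its call without CFPAC-1 DMSO replicates 1 or 2, IKE replicates 1 or 2, or PANC-1 IKE replicate 3 (adjusted p from 0.05 to 0.221), and ABCB1 without CFPAC-1 DMSO replicates 1 or 2, or IKE replicate 2 (adjusted p from 0.0635 to 0.124). PLCXD2 lost its call without any 1 library other than CFPAC-1 IKE replicate 1 (adjusted p from 0.0562 to 0.185), and P2RX5-TAX1BP3 without CFPAC-1 DMSO replicates 1 or 2, IKE replicate 1, PANC-1 DMSO replicates 1 or 2, or IKE replicate 3 (adjusted p from 0.0517 to 0.217).

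The ATF4 amino acid response list, genes for amino acid synthesis, uptake and stress, rose as a group in CFPAC-1. Of its 37 tested members, 26 rose, 0 fell and 11 were not called, or 33 risen adjusted over the list alone (median log2 fold change 0.96, camera adjusted p = 2.31e-62, and adjusted p = 0.00742 with an estimated correlation). List p-values are from camera, a test of whether the members of a list moved more than other genes. They use the preset correlation unless an estimated one is named. Among genes that load amino acids onto tRNA, the aminoacyl tRNA synthetases, 11 of 21 rose and 0 fell, or 13 risen and 1 fallen adjusted over the list alone (median 0.41, camera adjusted p = 9.85e-16). They were led by GARS1 (1.19, adjusted p = 2.98e-06), AARS1 (1.09, adjusted p = 8.49e-06), YARS1 (0.96, adjusted p = 4.03e-05) and the tRNA exporter gene XPOT (0.89, adjusted p = 4.34e-05). NRF2 targets, the oxidative stress genes of the factor encoded by NFE2L2, had 18 of 32 members risen, 0 fallen and 14 not called, or 27 risen adjusted over the list alone (median 0.58, camera adjusted p = 3.53e-36). They included the aldo-keto reductase gene AKR1B10 (1.35, adjusted p = 5.55e-05), GCLC of glutathione synthesis (1.34, adjusted p = 9.04e-05), the ferritin light chain gene FTL (0.77, adjusted p = 1.23e-04) and the quinone reductase gene NQO1 (0.72, adjusted p = 2.16e-04). Risen NRF2 targets numbered 9 to 10 without CFPAC-1 DMSO replicates 1 or 2, or IKE replicate 1.

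G2/M genes, which act in mitosis, fell as a list in CFPAC-1. Of 31 G2/M genes, 13 fell, 0 rose and 18 were not called, or 25 fallen adjusted over the list alone (median -0.39, camera adjusted p = 1.75e-26). The cyclin gene CCNB1 fell from 82.7 ± 1.87 to 60.7 ± 0.141 FPKM (log2 fold change -0.44, SE 0.07, adjusted p = 0.0118, limma), and the spindle checkpoint kinase gene BUB1 fell too (-0.47, adjusted p = 0.0129). Neither call held throughout when single libraries were left out, while both signs did. CCNB1 lost its call without CFPAC-1 DMSO replicates 1 or 2, or IKE replicates 1 or 2. BUB1 lost it without CFPAC-1 DMSO replicates 1 or 2, or IKE replicate 2. Each of these fits leaves an arm with 1 library, which also lowers the power. Fallen G2/M genes numbered 0 to 8 without CFPAC-1 DMSO replicates 1 or 2, IKE replicates 1 or 2, or PANC-1 DMSO replicates 1 or 2, while the list passed each time. Of 31 G1/S and DNA replication genes, 1 fell (0 to 2 without CFPAC-1 DMSO replicates 1 or 2, IKE replicate 2, or PANC-1 IKE replicate 2) and 0 rose (1 without PANC-1 IKE replicate 2), or 4 fallen and 1 risen adjusted over the list alone. Their camera adjusted p = 0.00187 became adjusted p = 0.205 with an estimated correlation, and 0.0915 without CFPAC-1 DMSO replicate 1. Replication-dependent histone genes gave 0 single calls of 23 with limma at either adjustment, and 4 down and 0 up at an unadjusted p (camera adjusted p = 0.00310, and adjusted p = 0.531 with an estimated correlation). Of 26 hypoxia targets, 4 rose, 0 fell and 22 were not called, or 9 risen adjusted over the list alone (median 0.22, camera adjusted p = 1.50e-08). They included DDIT4, a repressor of mTORC1 signalling (0.94, adjusted p = 0.00226), and the angiogenic factor gene VEGFA (1.02, adjusted p = 0.00839), which lost its call without CFPAC-1 DMSO replicate 1, or IKE replicates 1 or 2 (adjusted p from 0.0674 to 0.0922). Risen hypoxia targets numbered 1 to 2 without CFPAC-1 DMSO replicates 1 or 2, or IKE replicates 1 or 2. Of 28 genes of glycolysis and the pentose phosphate route, 3 rose and 0 fell, or 6 risen adjusted over the list alone. Risen members numbered 1 without CFPAC-1 DMSO replicate 2. The camera adjusted p = 1.78e-04 of this list became adjusted p = 0.404 with an estimated correlation. Cholesterol synthesis genes gave 0 single calls of 25 with limma, and 3 without PANC-1 IKE replicate 2. At an unadjusted p 11 were up and 0 down, and 6 had risen adjusted over the list alone (median 0.19, camera adjusted p = 2.26e-07, and adjusted p = 0.128 with an estimated correlation).

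Ferroptosis genes were tested as lists in CFPAC-1 too. Of 36 ferroptosis suppressors, 5 rose, 0 fell and 31 were not called, or 7 risen and 1 fallen adjusted over the list alone (median 0.08, camera adjusted p = 0.00268). The risen members were led by FTL, by SLC3A2, which encodes the heavy chain that partners SLC7A11 (0.96, adjusted p = 3.39e-04), and by the thioredoxin reductase gene TXNRD1 (0.76, adjusted p = 0.00189). Of 37 ferroptosis drivers, 5 rose and 0 fell, or 7 risen adjusted over the list alone, led by CHAC1 and the glutamine carrier gene SLC1A5 (1.08, adjusted p = 1.87e-04). Their camera adjusted p = 0.00751 became adjusted p = 0.128 with an estimated correlation, and 0.0619 without CFPAC-1 DMSO replicate 1. Of 29 iron and haem genes, 3 rose and 0 fell, or 3 risen and 2 fallen adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.128 with an estimated correlation). Of 33 glutathione genes, 4 rose and 1 fell, or 7 risen and 3 fallen adjusted over the list alone (camera adjusted p = 0.00708, and adjusted p = 0.205 with an estimated correlation). Fewer suppressors, 3 without CFPAC-1 DMSO replicates 1 or 2, or IKE replicates 1 or 2, were called as risen, 1 fell without PANC-1 IKE replicate 2, and their median was 0.05 without CFPAC-1 IKE replicate 2. The fallen glutathione gene was not called (0 without CFPAC-1 DMSO replicates 1 or 2, IKE replicates 1 or 2, or PANC-1 DMSO replicates 1 or 2). Risen drivers numbered 2 to 3 without CFPAC-1 DMSO replicates 1 or 2, IKE replicates 1 or 2, or PANC-1 DMSO replicates 1 or 2, and risen iron and haem genes 1 without CFPAC-1 DMSO replicates 1 or 2, or IKE replicates 1 or 2. In CFPAC-1 the ATF4 (adjusted p = 0.00742), synthetase (0.00742), NRF2 (0.00624), G2/M (0.0372), hypoxia (0.0398) and suppressor (0.0476) lists kept their calls in camera with an estimated correlation, at larger p-values. These lists share members and are not separate results. The suppressors FTL, FTH1 and TXNRD1 are also NRF2 targets. The suppressor SLC3A2, the hypoxia target DDIT4 and the drivers CHAC1 and SLC1A5 are also on the ATF4 list. Across all genes, limma called 173 in this line, of which 113 rose and 60 fell. The count was 108 without CFPAC-1 DMSO replicate 1, 80 without DMSO replicate 2, 107 without IKE replicate 1 and 85 without IKE replicate 2.

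The second comparison asked the same of PANC-1 cells that survived 1 µM IKE. HMOX1, the haem-degrading oxygenase (ENSG00000100292, chromosome 22, 35380361 to 35394214), rose from 19.5 ± 0.898 FPKM (SD, n = 2) to 137 ± 52.3 FPKM (SD, n = 4; log2 fold change 2.67, SE 0.27, adjusted p = 8.20e-04, limma), and its 4 IKE libraries held 182, 97.3, 86.4 and 182 FPKM. S100P rose from 0.550 ± 0.0566 to 4.02 ± 0.708 FPKM (log2 fold change 1.68, SE 0.18, adjusted p = 0.00126), and ASNS from 50.1 ± 3.92 to 133 ± 12.9 FPKM (log2 fold change 1.39, SE 0.09, adjusted p = 6.64e-05). OSGIN1, an oxidative stress growth inhibitor gene (1.3, adjusted p = 8.20e-04), PCK2, a mitochondrial enzyme of gluconeogenesis (1.28, adjusted p = 2.71e-04), and PSAT1 (1.10, adjusted p = 2.05e-04) rose as well. SLC7A11, the cystine-transporting chain of system xc- (ENSG00000151012, chromosome 4, 138164097 to 138242349), rose from 5.48 ± 0.283 to 12.8 ± 2.92 FPKM (log2 fold change 1.07, SE 0.15, adjusted p = 0.00538), and lost its call without PANC-1 DMSO replicate 1 (adjusted p = 0.0809). The growth factor response gene EGR1 rose by 1.20 on the log2 scale (adjusted p = 0.00413) and lost its call without PANC-1 DMSO replicate 1 (adjusted p = 0.0547). The growth factor gene HGF fell from 15.1 ± 0.198 to 8.30 ± 0.353 FPKM (log2 fold change -0.80, SE 0.08, adjusted p = 9.56e-04). Other large falls kept their sign, but not always their call, with single libraries left out. Leaving out a PANC-1 DMSO library leaves 1 in that arm, which also lowers the power. The histone gene H1-3 (-0.86, adjusted p = 0.00747) lost its call without PANC-1 DMSO replicates 1 or 2 (adjusted p from 0.0522 to 0.125), the death ligand gene TNFSF10 (-0.76, adjusted p = 0.00555) without PANC-1 DMSO replicates 1 or 2 (adjusted p from 0.0582 to 0.0662), and the collagen gene COL7A1 (-0.68, adjusted p = 0.00436) without PANC-1 DMSO replicate 2 (adjusted p = 0.0662). The fatty acid elongase gene ELOVL6 (-0.70, adjusted p = 0.0247) lost its call without PANC-1 DMSO replicates 1 or 2 (adjusted p from 0.110 to 0.228), and ICAM5 (-0.72, adjusted p = 0.0190) without PANC-1 DMSO replicate 1 (adjusted p = 0.230). POLN (-0.76, adjusted p = 0.0365) lost its call without CFPAC-1 IKE replicates 1 or 2, PANC-1 DMSO replicates 1 or 2, or IKE replicates 2 or 3 (adjusted p from 0.0505 to 0.257), and ASB4 (-0.76, adjusted p = 0.0361) without any 1 library other than PANC-1 IKE replicate 2 (adjusted p from 0.0538 to 0.195).

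Stress lists rose in PANC-1. The ATF4 list had 21 members risen, 1 fallen and 15 not called of 37, or 32 risen and 1 fallen adjusted over the list alone (median 0.48, camera adjusted p = 8.75e-31). PHGDH rose by 1.06 on the log2 scale (adjusted p = 1.82e-04) and CBS by 0.92 on the log2 scale (adjusted p = 1.82e-04). The count of risen members was 11 to 12 without PANC-1 DMSO replicates 1 or 2, and that of fallen members 0 without any 1 library other than PANC-1 IKE replicate 2. Of 21 synthetase genes, 12 rose and 0 fell, as many adjusted over the list alone (median 0.30, camera adjusted p = 1.20e-15), led by GARS1 (0.88, adjusted p = 6.64e-05), WARS1 (0.67, adjusted p = 2.05e-04) and SARS1 (0.53, adjusted p = 8.20e-04). Of 32 NRF2 targets, 15 rose, 0 fell and 17 were not called, or 23 risen adjusted over the list alone (median 0.32, camera adjusted p = 5.13e-21). FTL rose by 0.78 on the log2 scale (adjusted p = 1.45e-04) and TXNRD1 by 0.73 on the log2 scale (adjusted p = 0.00191). Fewer synthetase genes, 6 without PANC-1 DMSO replicate 1, and fewer NRF2 targets, 6 to 7 without PANC-1 DMSO replicates 1 or 2, were called as risen. The unfolded protein response list had 6 of 24 genes risen and 0 fallen, or 12 risen and 1 fallen adjusted over the list alone (median 0.22, camera adjusted p = 1.02e-07). Its member HSPA5, which encodes the chaperone BiP of the endoplasmic reticulum, rose by 0.51 on the log2 scale (adjusted p = 0.00199). Of 20 heat shock genes, 4 rose and 0 fell, or 7 risen adjusted over the list alone (median 0.17, camera adjusted p = 2.46e-07). They included HSPA1B (0.66, adjusted p = 0.00385), whose near-identical copy HSPA1A makes the split of reads uncertain, and which lost its call without PANC-1 DMSO replicate 1 (adjusted p = 0.0547). Risen heat shock genes numbered 0 to 1 without PANC-1 DMSO replicates 1 or 2, and risen unfolded protein response genes 1 to 3 without CFPAC-1 IKE replicates 1 or 2, PANC-1 DMSO replicates 1 or 2, or IKE replicate 1. The unfolded protein response median was 0.14 without PANC-1 DMSO replicate 1, and 1 of its genes fell without PANC-1 IKE replicate 3.

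Immediate early and cell division genes were tested as lists in PANC-1. Of 27 immediate early genes, which respond first to growth factors and stress, 11 rose, 0 fell and 16 were not called, or 19 risen adjusted over the list alone. Their camera adjusted p = 1.20e-15 became adjusted p = 0.0994 with an estimated correlation, and adjusted p was 0.00771 with fry. The risen number was 1 to 6 without any 1 library other than PANC-1 IKE replicates 2 and 3. CCN1, a matricellular protein gene on this list, rose from 91.8 ± 4.64 to 164 ± 16.8 FPKM (log2 fold change 0.82, SE 0.09, adjusted p = 9.56e-04, limma). The YAP and TAZ list, which also holds CCN1, had 3 of 24 genes risen and 0 fallen, or 6 risen and 1 fallen adjusted over the list alone (median 0.15, camera adjusted p = 0.00104). Of 31 G2/M genes, 16 fell, 0 rose and 15 were not called, or 30 fallen adjusted over the list alone (median -0.35, camera adjusted p = 3.46e-26). The mitotic kinase gene CDK1 fell from 63.8 ± 2.33 to 44.2 ± 2.27 FPKM (-0.52, adjusted p = 0.00346) and lost its call without PANC-1 DMSO replicate 1 (adjusted p = 0.0669). Fallen G2/M genes numbered 0 to 2 without PANC-1 DMSO replicates 1 or 2, and risen YAP and TAZ genes 1 without PANC-1 DMSO replicate 1 (median 0.10), while both lists passed each time. Of 23 replication-dependent histone genes, whose close similarity makes single values uncertain, 7 fell, 0 rose and 16 were not called, or 17 fallen adjusted over the list alone. The fallen number was 0 to 11 without CFPAC-1 IKE replicates 1 or 2, PANC-1 DMSO replicates 1 or 2, or IKE replicates 1, 2 or 4. For the histone list the camera adjusted p = 1.12e-13 became adjusted p = 0.101 with an estimated correlation, and adjusted p was 0.0163 with fry. Of 31 G1/S and DNA replication genes, 1 fell (0 to 4 without any 1 library other than CFPAC-1 IKE replicates 1 and 2) and 0 rose, or 10 fallen and 1 risen adjusted over the list alone (camera adjusted p = 1.02e-06, and adjusted p = 0.0502 with an estimated correlation).

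Ferroptosis and lipid genes were read as lists in PANC-1 too. Of 36 suppressors, 7 rose and 0 fell, or 9 risen and 3 fallen adjusted over the list alone (camera adjusted p = 0.00942, and adjusted p = 0.0502 with an estimated correlation). Of 37 drivers, 3 rose and 0 fell, or 5 risen adjusted over the list alone, and the list did not pass (camera adjusted p = 0.129). Of 29 iron and haem genes, 5 rose and 0 fell, or 9 risen and 2 fallen adjusted over the list alone (camera adjusted p = 0.00171, and adjusted p = 0.0502 with an estimated correlation). Of 25 cholesterol synthesis genes, 4 fell and 0 rose, or 8 fallen adjusted over the list alone (camera adjusted p = 1.59e-06, and adjusted p = 0.101 with an estimated correlation). Fallen cholesterol genes numbered 0 to 7 without any 1 library other than PANC-1 IKE replicate 3. INSIG1 of this list, which holds back sterol synthesis, fell (-0.40, adjusted p = 0.0233) and lost its call without PANC-1 DMSO replicates 1 or 2 (adjusted p from 0.0910 to 0.242). Of 29 genes of fatty acid synthesis and remodelling, 1 rose and 2 fell, or 2 risen and 9 fallen adjusted over the list alone. Their camera adjusted p = 0.00325 became adjusted p = 0.232 with an estimated correlation, and 0.133 without PANC-1 DMSO replicate 1. The 13 mitochondrially encoded mRNAs gave 0 single calls with limma at either adjustment and 2 at an unadjusted p, while 12 had a positive log2 fold change (median 0.34, or 0.11 to 0.66 without PANC-1 DMSO replicates 1 or 2, or IKE replicate 3). For them the camera adjusted p = 0.00270 became adjusted p = 0.527 with an estimated correlation, 0.084 with quantile normalization, 0.19 with PANC-1 IKE replicates 1 and 2 alone and 0.974 without PANC-1 DMSO replicate 1, where they held 2.80% of FPKM. A suppressor fell without PANC-1 IKE replicate 2, and an iron and haem gene without IKE replicate 3. Risen suppressors numbered 4 without PANC-1 DMSO replicate 1, risen drivers 1 without PANC-1 DMSO replicates 1 or 2, and risen iron and haem genes 3 without PANC-1 DMSO replicates 1 or 2. Fallen fatty acid genes numbered 0 to 6 without PANC-1 DMSO replicates 1 or 2, or IKE replicate 2, and risen ones 0 to 2 without PANC-1 DMSO replicates 1 or 2, or IKE replicate 2. Across all genes, limma called 311 in this line, of which 158 rose and 153 fell. The balance was 106 risen and 66 fallen with PANC-1 IKE replicates 1 and 2 alone, 197 and 274 with replicates 3 and 4 alone, and 50 and 13 with the replicate block. Without PANC-1 DMSO replicate 1 or 2, more rises than falls remained. The count was 42 without PANC-1 DMSO replicate 1, 75 without DMSO replicate 2, 504 without IKE replicate 2, 175 without IKE replicate 4 and 203 without either CFPAC-1 IKE replicate 1 or 2. In PANC-1 9 lists kept their calls in camera with an estimated correlation, at larger p-values. They were the ATF4 (adjusted p = 0.0233), synthetase (0.0096), NRF2 (0.0096), unfolded protein response (0.0096), G2/M (0.0233), heat shock (0.0314), YAP and TAZ (0.0314), ribosome biogenesis (0.0233) and ESCRT-III (0.0233) lists.

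**Figure D1:**
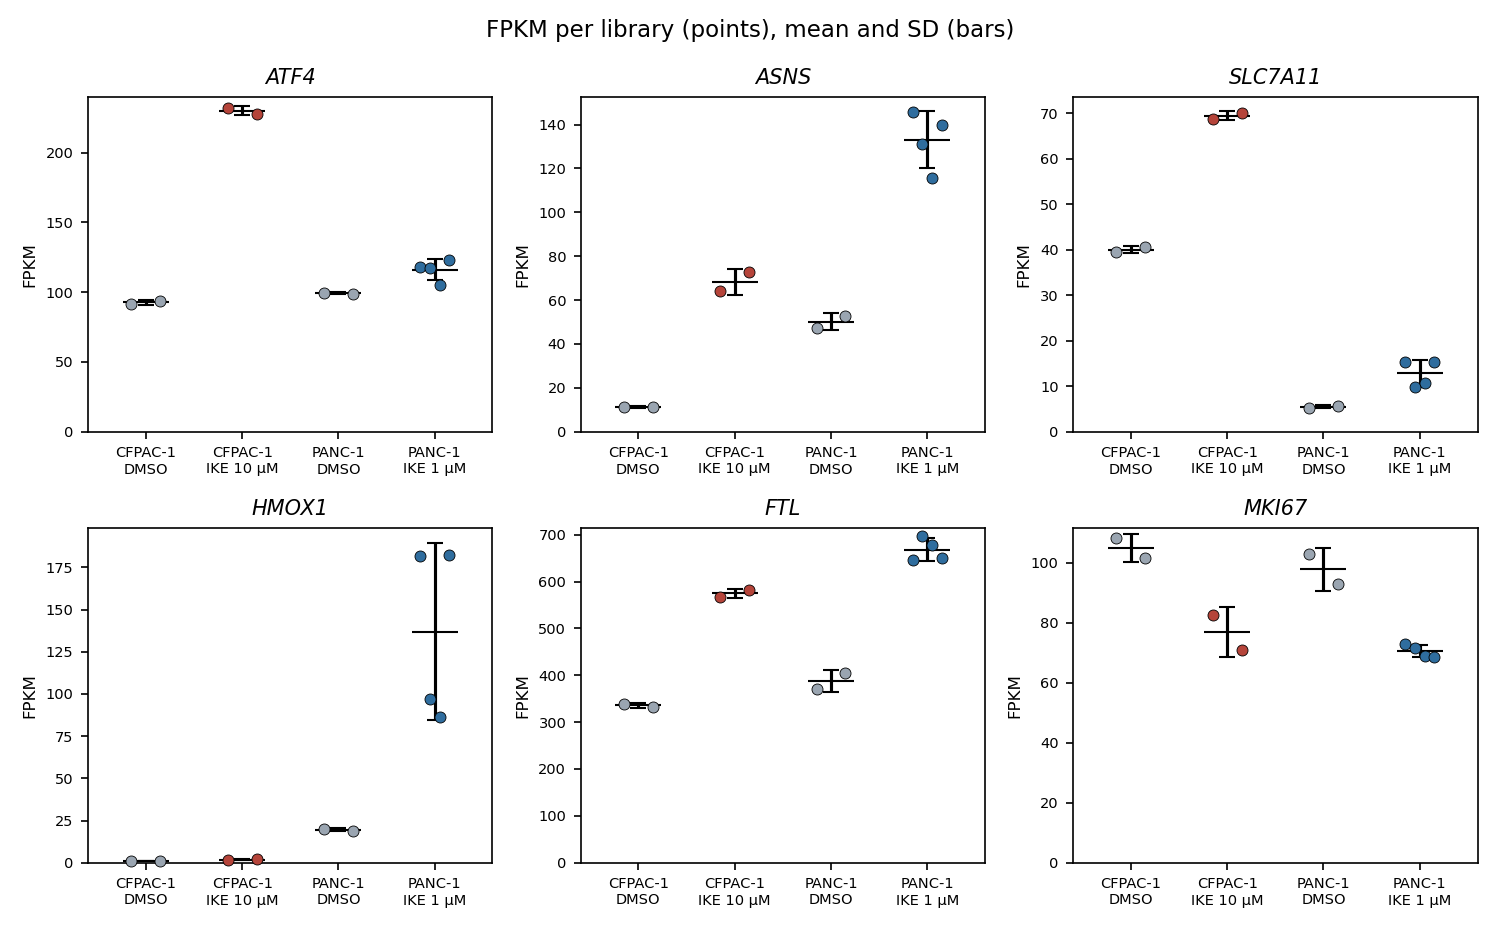
FPKM of 6 genes in each library, with points for libraries, horizontal lines for group means and bars for the SD (n = 2, or 4 in PANC-1 with IKE), and a vertical axis in FPKM from 0. ATF4 reached 230.0 FPKM in CFPAC-1 with IKE against 92.7 with DMSO, and HMOX1 in PANC-1 with IKE spread from 86.4 to 182 FPKM.

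A panel of 21 genes of cystine supply, glutathione, iron and lipid peroxidation was read in both lines. In CFPAC-1 10 rose, 0 fell and 11 were not called by limma, and in PANC-1 9 rose, 0 fell and 12 were not called. ASNS, TRIB3, SLC3A2, FTL, FTH1 and NQO1 rose in both lines. TRIB3, which encodes a pseudokinase of the ATF4 response, rose by 1.48 on the log2 scale (adjusted p = 3.91e-05) in CFPAC-1 and 0.69 on the log2 scale (adjusted p = 0.00528) in PANC-1. The ferritin chain genes FTL (ENSG00000087086, chromosome 19, 48965301 to 48966878) and FTH1 rose by 0.77 and 0.60 in CFPAC-1 and by 0.78 and 0.73 in PANC-1, and both have processed pseudogenes that can share their reads. CHAC1, ATF4, SESN2 and TFRC rose in CFPAC-1, and SLC7A11, HMOX1 and GCLM rose in PANC-1. Of these 7, the response itself differed between the lines for CHAC1 (-1.48, adjusted p = 0.0176) and ATF4 (-1.08, adjusted p = 0.00146), and CHAC1 lost that call without CFPAC-1 DMSO replicates 1 or 2, IKE replicates 1 or 2, or PANC-1 DMSO replicate 2 (adjusted p from 0.0579 to 0.101). HMOX1 (2.15, adjusted p = 0.0588), SESN2 (-0.40, adjusted p = 0.403), TFRC (-0.19, adjusted p = 0.410), SLC7A11 (0.29, adjusted p = 0.657) and GCLM (0.16, adjusted p = 0.843) did not pass that test. With DMSO, HMOX1 stood much lower in CFPAC-1 than in PANC-1, so adding 1 FPKM may understate its change in CFPAC-1. SLC7A11 stood at 40 ± 0.728 FPKM in CFPAC-1 with DMSO and 69.4 ± 0.948 with IKE, which did not pass (0.78, adjusted p = 0.0593), and passed without PANC-1 IKE replicates 1, 2 or 4 (adjusted p from 0.0266 to 0.0455) and in a fit of that line alone (9.10e-04). GPX4, the lipid peroxide reductase gene (-0.04 in CFPAC-1 and -0.10 in PANC-1), ACSL4, which activates polyunsaturated fatty acids (0.02 and -0.05), and AIFM2 (0.26 and 0.36) were not called in either line. Nor were PTGS2 (0.28 and 0.00), SLC40A1 (0.17 and -0.09), MGST1 (0.29 and 0.24), the stress factor genes ATF3 (0.34 and 1.19) and DDIT3 (0.33 and 0.40). In CFPAC-1 the calls of SESN2, TFRC and FTH1 were lost without any 1 of the 4 CFPAC-1 libraries, DMSO replicates 1 and 2 and IKE replicates 1 and 2 (adjusted p from 0.0652 to 0.0980, 0.0775 to 0.145 and 0.0626 to 0.191). In PANC-1 GCLM, SLC3A2 and NQO1 lost their calls without PANC-1 DMSO replicate 1 (adjusted p = 0.135, 0.121 and 0.0582) or 2 (0.136, 0.114 and 0.0903), and TRIB3 and SLC7A11 without replicate 1 (0.0778 and 0.0809). Without PANC-1 IKE replicate 3, ATF3 (0.0264), ATF4 (0.0293), DDIT3 (0.0376) and SESN2 (0.0119) passed in PANC-1, as did ATF3 without IKE replicate 2 (0.0420).

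**Figure D2:**
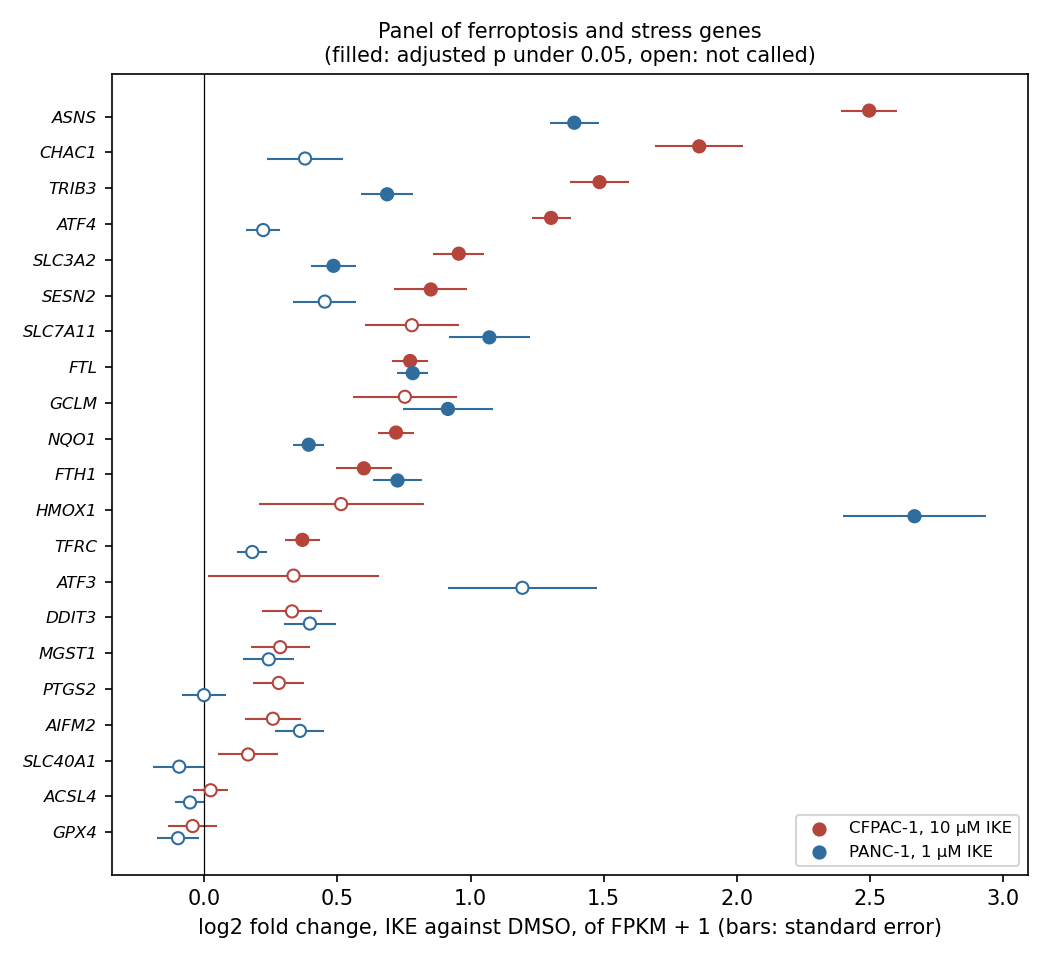
Log2 fold change of FPKM + 1 with IKE for the 21 panel genes, with points for the limma estimates in CFPAC-1 (10 µM) and PANC-1 (1 µM), bars for the standard error, and filled points where adjusted p was under 0.05. ASNS lies at 2.50 in CFPAC-1 and 1.39 in PANC-1, and GPX4 and ACSL4 lie between -0.10 and 0.02 in both lines.

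The third comparison asked which genes changed in both lines, which share no control libraries. ASNS, CBS, PHGDH, PSAT1, GARS1 and FTL, with the values above, had the smallest p among genes that rose in both. The cell division genes BUB1, CCNA2, ANLN and MKI67, the kinetochore gene NUF2 and the surface glycoprotein gene CD24 had the smallest p among genes that fell in both, with -0.54 in CFPAC-1 and -0.63 in PANC-1 for NUF2 and -0.37 and -0.38 for CD24. In all, 48 genes rose in both lines against 1.37 expected for independent lists (Fisher's exact test, one-sided p = 4.13e-64), and 12 fell in both against 0.702 (the same exact test, p = 3.68e-12). Genes are not independent replicates, and the lines share 1 estimate of the spread per gene, so their calls are not independent. With the replicate block 28 genes rose in both and 0 fell, and without PANC-1 IKE replicate 2 these were 55 and 33. Most of the 12 falls were lost without any 1 CFPAC-1 library or any 1 DMSO library of PANC-1. LIPG, P4HA1 and DDIT4, the 3 genes called in opposite directions and singled out after their values were seen, rose in CFPAC-1 (0.52, 0.42 and 0.94) and fell in PANC-1 (-0.41, -0.32 and -0.47). In PANC-1 LIPG lost its call without PANC-1 DMSO replicates 1 or 2, or IKE replicates 1 or 4 (adjusted p from 0.0571 to 0.242), P4HA1 without any 1 library other than PANC-1 IKE replicates 2 and 4 (adjusted p from 0.0528 to 0.306), and DDIT4 without any 1 library other than PANC-1 IKE replicate 2 (adjusted p from 0.0707 to 0.314). In CFPAC-1 LIPG lost its call without CFPAC-1 DMSO replicates 1 or 2, or IKE replicates 1 or 2 (adjusted p from 0.0587 to 0.171), and P4HA1 without CFPAC-1 DMSO replicates 1 or 2, or IKE replicates 1 or 2 (adjusted p from 0.0935 to 0.18). Of the 6 genes that fell in both, all 6 lost the CFPAC-1 call without CFPAC-1 DMSO replicate 1 (adjusted p from 0.0796 to 0.167) or IKE replicate 2 (0.117 to 0.204). ANLN, BUB1, MKI67 and NUF2 lost it without DMSO replicate 2 (0.0758 to 0.183), and ANLN, CCNA2, CD24 and NUF2 without IKE replicate 1 (0.0658 to 0.167). All 6 lost the PANC-1 call without PANC-1 DMSO replicate 1 (0.0851 to 0.219), and ANLN, BUB1, CCNA2 and CD24 without DMSO replicate 2 (0.0670 to 0.0894). Across the 13077 genes the log2 fold changes of the lines had Pearson r = 0.212 and Spearman rho = 0.136. The 60 genes changed the same way became 39, 35, 37 and 33 without CFPAC-1 DMSO replicate 1, DMSO replicate 2, IKE replicate 1 and IKE replicate 2, then 23 and 26 without PANC-1 DMSO replicates 1 and 2, and 88 was the count without PANC-1 IKE replicate 2.

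**Figure D3:**
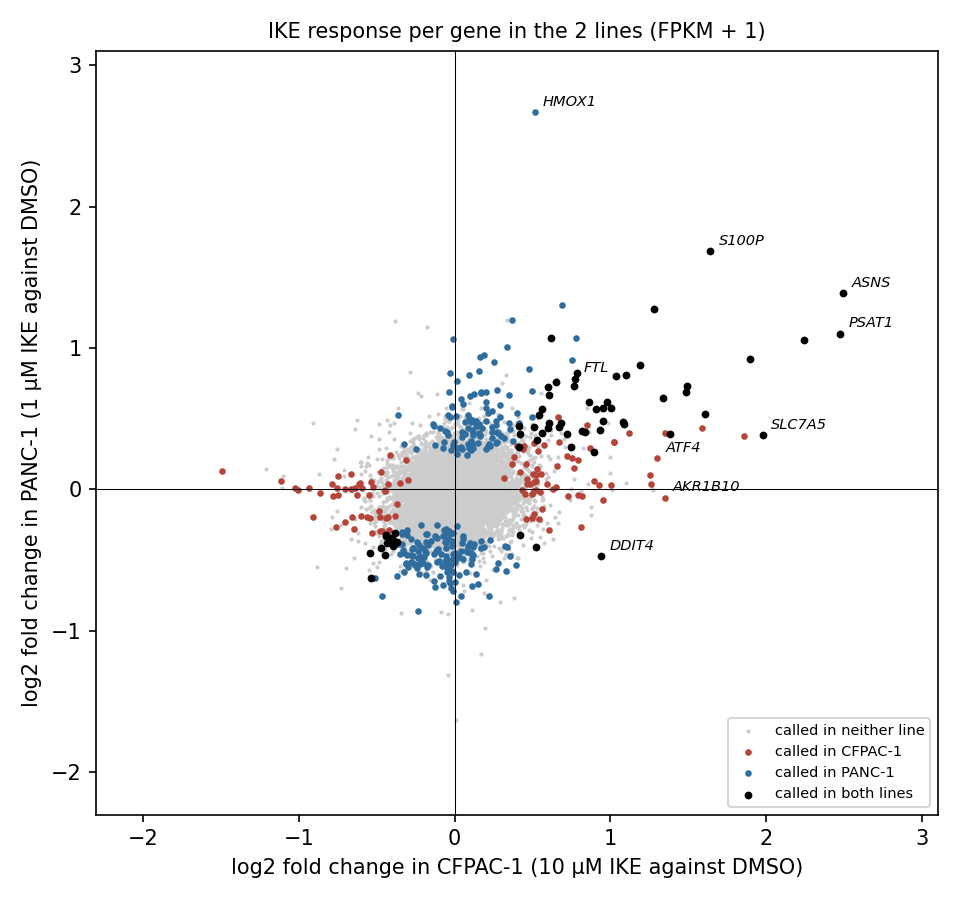
Log2 fold change of FPKM + 1 with IKE in CFPAC-1 (horizontal axis) and in PANC-1 (vertical axis) for 13077 genes, each a point coloured by the line or lines in which limma called it. The 48 genes that rose in both lines lie to the upper right, ASNS at 2.50 and 1.39, and DDIT4 lies at 0.94 and -0.47.

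The fourth comparison tested the difference of the IKE response, PANC-1 minus CFPAC-1, and because line and dose changed together it cannot assign a difference to either. The leucine carrier gene SLC7A5 differed by -1.59 (SE 0.12, adjusted p = 6.61e-04, limma), with 9.82 ± 0.580 FPKM with DMSO and 41.7 ± 1.78 with IKE in CFPAC-1 (SD, n = 2) against 73.5 ± 2.90 and 96.5 ± 8.49 in PANC-1. ATF4 differed by -1.08 (SE 0.10, adjusted p = 0.00146), PSAT1 by -1.37 on the log2 scale (adjusted p = 0.00281), PHGDH by -1.18 on the log2 scale (adjusted p = 0.00318). MTHFD2, of mitochondrial folate metabolism, differed by -0.99 on the log2 scale (adjusted p = 0.00318). AKR1B10 differed too (-1.41, adjusted p = 0.00281), with 0.0950 FPKM in PANC-1 with DMSO. WDR49 (1.17, adjusted p = 0.0176) and COL8A1 (1.0, adjusted p = 0.0131), which fell in CFPAC-1, stood at 0.0400 and 0.0250 FPKM in PANC-1 with DMSO. WDR49 lost its call without CFPAC-1 DMSO replicates 1 or 2, IKE replicate 2, or PANC-1 DMSO replicates 1 or 2 (adjusted p from 0.0620 to 0.0823), and COL8A1 without PANC-1 DMSO replicates 1 or 2 (adjusted p from 0.0676 to 0.0813). Of the 37 ATF4 list genes, 10 had a lower response in PANC-1, 0 a higher one and 27 were not called, or 22 lower and 3 higher adjusted over the list alone (median -0.51, camera adjusted p = 2.68e-18, and adjusted p = 0.0897 with an estimated correlation). Of 25 cholesterol synthesis genes, 1 had a lower response and 0 a higher one, or 14 lower adjusted over the list alone (median -0.31, camera adjusted p = 2.37e-13, and adjusted p = 0.0897 with an estimated correlation). Of 26 hypoxia targets, 3 had a lower response and 0 a higher one, or 8 lower adjusted over the list alone (median -0.28, camera adjusted p = 4.45e-06, and adjusted p = 0.0897 with an estimated correlation). Hypoxia targets with a lower response numbered 1 without CFPAC-1 DMSO replicate 2, IKE replicates 1 or 2, or PANC-1 DMSO replicate 1, and cholesterol genes 0 to 5 without any 1 library other than PANC-1 IKE replicates 3 and 4. No list kept its call with an estimated correlation, while fry passed the ATF4 (adjusted p = 0.00885), cholesterol (0.00885) and hypoxia (0.0103) lists. Across all genes limma called 44, 14 with a higher and 30 with a lower response in PANC-1. With PANC-1 IKE replicates 1 and 2 alone 4 were higher and 13 lower, with replicates 3 and 4 alone 15 and 54, and with the replicate block 0 and 2. The count was 19, 13, 23 and 14 without CFPAC-1 DMSO replicate 1, DMSO replicate 2, IKE replicate 1 and IKE replicate 2, and 14 and 19 without PANC-1 DMSO replicates 1 and 2.

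The last comparison set PANC-1 against CFPAC-1 with DMSO, as the background of the responses. CEACAM6, an epithelial adhesion gene, stood at 219.5 ± 7.99 FPKM in CFPAC-1 and 0.330 ± 0.141 in PANC-1 (SD, n = 2; log2 difference -7.38, SE 0.13, adjusted p = 1.03e-12, limma). RAB25, a vesicle transport gene, differed by -6.32. Of 25 epithelial genes, 23 were lower and 1 higher in PANC-1, as many adjusted over the list alone (median -3.29, camera adjusted p = 4.98e-10, and adjusted p = 0.115 with an estimated correlation). Of 28 type I interferon response genes, 25 were lower and 2 higher, as many adjusted over the list alone, among them the antiviral genes MX1 (-6.01), BST2 (-5.25) and IFI27 (-8.64). The interferon list had a camera adjusted p = 1.38e-08, and adjusted p = 0.115 with an estimated correlation. Of 28 ribosome biogenesis genes, 28 were higher in PANC-1, as many adjusted over the list alone (median 1.21, camera adjusted p = 3.41e-07, and 0.0376 with an estimated correlation). The nucleolar methyltransferase gene FBL, with the smallest p of this list, differed by 4.30, far above that median. Of 24 mesenchymal genes, 8 were higher and 14 lower (camera adjusted p = 0.239), with the matrix protease gene MMP2 at 5.86. SLC7A11 was lower in PANC-1 (-2.66, SE 0.18, adjusted p = 5.90e-08) and HMOX1 higher (3.43, SE 0.31, adjusted p = 9.19e-07). Of all genes 10286 differed, 5678 higher and 4608 lower in PANC-1. The median of all genes was 0.12 on the log2 scale and -0.06 after median-ratio scaling, where 4709 were higher and 5409 lower.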

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

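The tests of scaling, of the level without IKE, of 7SL reads and of the level of RPS29 against other ribosomal protein mRNAs below were chosen only after the results were seen, and the r of RPS29 with their mean before. The response to IKE differed between the lines, PANC-1 minus CFPAC-1 on the log2 scale, for 44 of all 13077 genes by a limma test of the difference itself. These include 31 of the 127 named genes, a share raised by the naming rule, which takes genes with the smallest p for this test and the largest changes in each line. Among amino acid and stress genes these were ATF4 (-1.08), CHAC1 (-1.48), ASNS (-1.11), PSAT1 (-1.37), PHGDH (-1.18), SLC7A5 (-1.59), CBS (-0.97), STC2 (-1.08), MTHFD2 (-0.99), AARS1 (-0.63) and XPOT (-0.63). Hypoxia and secreted protein genes gave DDIT4 (-1.42), P4HA1 (-0.74), STC1 (-0.96), COL7A1 (-0.79) and LIPG (-0.93), and lipid genes gave SCD (-0.67) and INSIG1 (-0.73). A smaller fall or a larger rise in PANC-1 was seen for CCN1 (0.86), NF2 (0.65), EZR (0.52), PMEL (0.84) and RASSF8 (0.66). Genes near 0 FPKM in 1 of the lines were AKR1B10 (-1.41), AKR1C3 (-0.68), CYP4F11 (-0.87), HGF (-0.80), WDR49 (1.17), IRAG2 (1.03), COL8A1 (1.00) and KCNJ15 (0.94). Of the 24 tested with libraries left out, ATF4, AKR1B10, CBS, DDIT4, MTHFD2, PHGDH, PSAT1 and SLC7A5 kept their call each time. The other 16 lost it in at least 1 case, 14, 15, 12 and 15 of them without CFPAC-1 DMSO replicate 1, DMSO replicate 2, IKE replicate 1 and IKE replicate 2, and 15 and 13 without PANC-1 DMSO replicates 1 and 2, with adjusted p from 0.0517 to 0.185. Among them AKR1C3 lost it also without PANC-1 IKE replicates 1, 3 or 4, CYP4F11 without IKE replicate 1, SCD without IKE replicate 4 and STC1 without any of the 4.

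The larger response of the ATF4 amino acid list in CFPAC-1 had a median difference of -0.51 (camera adjusted p = 2.68e-18, adjusted p = 0.0897 with an estimated correlation, and 0.00885 with fry). It depends on the test and is not established as a list. This response was weighed against technical explanations. Under 3 other scalings of the libraries the median difference was -0.513 or further from 0, which argues against scaling. A higher level of these genes in PANC-1 without IKE, leaving less room to rise, remains a candidate explanation. The 12 members not higher there had a median difference of -0.249 (bootstrap 95% interval -0.655 to -0.004, 10 of 12 negative), against -0.604 for the other 25. The DMSO values that made this split also enter the difference with the opposite sign, so error in them pushes the 2 sets apart. The bootstrap resampled genes, which can move together, and not libraries. For these reasons too, the 2 readings cannot be told apart. The dose, 10 µM in CFPAC-1 and 1 µM in PANC-1, is confounded with the line and stays open, as does a difference of the lines themselves, which was not tested. Only surviving cells were measured, so selection of survivors, which may differ between the lines, also stays open and was not tested.

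RPS29, a ribosomal protein gene, and PTPRD, a receptor phosphatase gene, stood at 9972 to 20362 and 5481 to 9887 FPKM. A high level of ribosomal protein genes in general is argued against in CFPAC-1, where RPS29 lay at least 6.78 times above the highest of 85 other ribosomal protein mRNAs in each library. In PANC-1 the ratio was only 1.44 or more, since RPS16 reached 10478 FPKM there. The median of the 85 was 348 to 451 FPKM in PANC-1 libraries, so such levels were not general there either. A level like that of RPS16 stays open for RPS29 in PANC-1, and PTPRD is not a ribosomal protein gene. The r of RPS29 with the mean of 39 of the 85 did not decide whether RPS29 followed them (0.522, permutation p = 0.122, adjusted 0.122, rho = 0.636, permutation p = 0.0545, adjusted 0.0545, and r = 0.243 without the 2 farthest libraries, or 0.475 within PANC-1, exact permutation p = 0.339). Copies of 7SL RNA, an abundant cytoplasmic RNA, lie inside RPS29 and PTPRD on the opposite strand and overlap 0 of their 21 and 331 annotated exons, and reads of them may account for these values: over 10 libraries the 2 genes had r = 0.894 (permutation p = 7.30e-04, adjusted 0.00146), rho = 0.855 (permutation p = 0.00325, adjusted 0.00650), r = 0.694 without the 2 farthest libraries and r = 0.917 within the 6 PANC-1 libraries (exact permutation p = 0.0167), and CFPAC-1 has only 4. A high level of either mRNA by itself stays open and was not tested.

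Among the 4 PANC-1 IKE libraries, 6 of 98 values examined had 1 library far from the other 3, with a gap to its neighbour, as a share of the range, that chance exceeds in about 1 in 20. The ratio was 0.839 for TK1, 0.897 for TNC, 0.858 for CCNG1 and 0.837 for LIPG, each in replicate 2. It was 0.940 for HERPUD1 in replicate 1 and 0.833 for CCNA2 in replicate 4.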

How the results depend on the processing

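Median-ratio scaling, PANC-1 IKE replicates 3 and 4 alone, RPS29 and PTPRD left out, and the settings of the lists and named genes other than those planned for them were tests chosen only after the results were seen. Counts are of called genes for CFPAC-1 (173), PANC-1 (311), the difference (44), PANC-1 against CFPAC-1 with DMSO (10286) and both lines (60). No gene called with IKE or for the difference had the opposite sign in another setting, while of the 10286 genes 39 did with quantile normalization, 27 with the replicate block and 17 with median-ratio scaling. With an absolute log2 fold change of at least 1, which only removes genes, they were 33, 12, 13, 4475 and 5. With the replicate number as a block, which leaves 2 residual degrees of freedom, they were 79 in CFPAC-1, 63 in PANC-1, 2 for the difference and 28 in both. Replicate differences of the arms correlated by -0.001 and 0.049 across genes, so no shared replicate effect was seen. The labels do not say whether the numbers pair the samples, and these correlations cannot show it. Quantile normalization gave 262 in CFPAC-1, the cause was not tested. A fit per line gave 189 in PANC-1. PANC-1 IKE replicates 1 and 2 alone gave 172 in PANC-1 and 17 for the difference, and replicates 3 and 4 alone gave 471 and 69, and the cause of the larger counts was not tested. No low-value filter, at least 5 FPKM, a pseudocount of 0.1, median-ratio scaling and RPS29 and PTPRD left out moved the CFPAC-1, PANC-1, difference and both-line counts by less than 1.5 times. With single libraries left out, counts ran from 80 to 256 in CFPAC-1, 42 to 504 in PANC-1, 13 to 62 for the difference, 9523 to 10452 with DMSO and 23 to 88 in both, and an arm left with 1 library was assumed to vary like the other groups. With an estimated correlation, lists past the threshold fell from 19 to 6 in CFPAC-1 and from 21 to 9 in PANC-1, and with libraries left out they were 16 to 20 and 18 to 23. Of the called named genes, 31 of 59 in CFPAC-1, 60 of 80 in PANC-1 and 16 of 24 for the difference lost their call with some library left out, 25, 44 and 22 with the replicate block, 29, 47 and 22 in at least 1 setting that leaves out no single library, and 3, 4 and 1 under another scaling. With PANC-1 IKE replicates 1 and 2 alone 13 of the 24 lost it. Lists whose estimated correlation lay below the preset 0.01 lost calls too. In PANC-1 the unadjusted camera p of ferroptosis suppressors (estimated correlation -0.018) went from 0.00542 to 0.0179. That of metallothioneins (estimated correlation -0.048) went from 0.0191 to 0.0501. Correlation between members alone therefore cannot account for all lost calls. Among lists that lost their call with an estimated correlation, fry passed some and not others. Cholesterol synthesis passed with fry (adjusted p = 0.0219 in CFPAC-1 and 0.0117 in PANC-1), while histones in CFPAC-1 did not (0.389). A second count-based tool, voom, relative log expression factors, library totals and a filter on counts per library need counts and were not run. Depth limits are unknown.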

Other observations

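All tests here were run on gene lists chosen before the data were examined, while their values with libraries left out, with the replicate block and with 2 PANC-1 IKE replicates were tests chosen only after the result was seen. In PANC-1, genes of membrane repair by ESCRT-III gave 0 single calls with limma of 19 (risen 1 without PANC-1 IKE replicate 2), at either adjustment, and 7 up at an unadjusted p, while 18 had a positive log2 fold change (median 0.14, camera adjusted p = 8.88e-05, and 0.0233 with an estimated correlation). Of 28 ribosome biogenesis genes in PANC-1, 1 rose and 0 fell, or 4 risen adjusted over the list alone (median 0.10, camera adjusted p = 8.88e-05, and 0.0233 with an estimated correlation), and the risen number was 0 to 2 without PANC-1 DMSO replicates 1 or 2, or IKE replicates 2 or 4. Of 39 cytosolic ribosomal protein mRNAs, 1 rose and 0 fell in PANC-1, or 7 risen adjusted over the list alone (median 0.13, camera adjusted p = 7.00e-10, and adjusted p = 0.120 with an estimated correlation). Of 31 autophagy and lysosome genes, 3 rose and 0 fell in PANC-1, or 7 risen adjusted over the list alone (camera adjusted p = 1.90e-06, and adjusted p = 0.0586 with an estimated correlation), and in CFPAC-1 1 rose and 0 fell, or 6 risen adjusted over the list alone (camera adjusted p = 0.00187, and adjusted p = 0.205 with an estimated correlation). In PANC-1 risen autophagy genes numbered 1 without PANC-1 DMSO replicates 1 or 2, or IKE replicate 4, and risen ribosomal protein mRNAs 0 to 7 without CFPAC-1 IKE replicates 1 or 2, PANC-1 DMSO replicates 1 or 2, or IKE replicates 1 or 4. The autophagy receptor gene SQSTM1 rose by 0.65 on the log2 scale (adjusted p = 0.00242) in CFPAC-1 and by 0.76 on the log2 scale (adjusted p = 8.20e-04) in PANC-1. Of 22 apoptosis regulators, 1 rose and 0 fell in PANC-1, or 2 risen adjusted over the list alone, or 2 without PANC-1 IKE replicate 2, and the list did not pass (camera adjusted p = 0.310). Its risen member was BCL2L1, a survival gene (0.52, adjusted p = 0.00221). Of 10 metallothionein and zinc genes, 1 rose and 0 fell in PANC-1, or 4 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.0301, adjusted p = 0.101 with an estimated correlation, and up to 0.0617 without PANC-1 DMSO replicate 1 or IKE replicate 4), and the risen number was 0 without PANC-1 DMSO replicates 1 or 2, or IKE replicate 4.

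In CFPAC-1, type I interferon genes gave 0 single calls with limma of 28 (fallen 1 without PANC-1 IKE replicate 2), 9 down and 0 up at an unadjusted p and 1 fallen adjusted over the list alone (median -0.16, or -0.07 without CFPAC-1 IKE replicate 2, where adjusted p = 0.0495, camera adjusted p = 9.12e-04, and adjusted p = 0.205 with an estimated correlation). Of 24 NF-kB and inflammatory genes in CFPAC-1, 0 rose and 1 fell, or 1 risen and 2 fallen adjusted over the list alone (camera adjusted p = 0.0312, adjusted p = 0.460 with an estimated correlation, and up to 0.100 without CFPAC-1 DMSO replicate 2 or IKE replicate 2, where none fell). Immediate early genes passed upward in CFPAC-1 too, with 1 of 27 risen and 0 fallen (camera adjusted p = 0.00840, and adjusted p = 0.582 with an estimated correlation). The p53 targets did not pass in CFPAC-1 (camera adjusted p = 0.491) or PANC-1 (0.445). Nuclear respiratory chain genes did not pass in CFPAC-1 (camera adjusted p = 0.107) or PANC-1 (0.133). They passed in CFPAC-1 without CFPAC-1 DMSO replicate 1 (0.00503), and in PANC-1 without PANC-1 DMSO replicate 2 (0.0237), with the replicate block (0.0117) and with PANC-1 IKE replicates 1 and 2 alone (0.025). Mesenchymal genes did not pass in CFPAC-1 (camera adjusted p = 0.417) or PANC-1 (0.933), where the median was negative and the mean and the test were positive. Epithelial genes did not pass in CFPAC-1 (camera adjusted p = 0.991), where the median and mean were negative and the test positive, or PANC-1 (0.296). Heat shock genes in CFPAC-1 had a positive median and test and a negative mean (camera adjusted p = 0.421), and NRF2 targets without IKE, PANC-1 against CFPAC-1, had a median of 0.08 and a mean of -0.19 (camera adjusted p = 0.980). Of 28 marker genes of other cell types, 9 of fibroblasts, endothelium and blood were expressed enough to test, and they did not pass in CFPAC-1 (camera adjusted p = 0.332) or PANC-1 (0.933), but passed in CFPAC-1 without DMSO replicate 1. Of 15 nuclear-retained RNAs 1 was tested, TUG1, with 0.06 in CFPAC-1 (camera adjusted p = 0.669) and 0.04 in PANC-1 (0.730).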
